A study of Mus musculus with 4 samples.

How the data were processed

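The material was skin of adult C57BL/6 mice, with 4 libraries in 4 groups: wild-type (WT) naive, Egr1 knockout (KO) naive, WT treated with house dust mite (HDM) and Egr1 KO treated with HDM. Each group held 1 library. According to the sample labels, hair was removed from the ear and neck area, sodium dodecyl sulfate (SDS), a detergent that disrupts the skin barrier, was applied to it and to both ears, and 100 mg of a cream with HDM extract followed once the skin had dried. This was done 2 times per week for 3 weeks. The treatment label of the naive groups reads SDS alone. Genotypes had been determined by PCR. Total RNA was extracted with Trizol, and 500 ng per library entered the QuantSeq 3′ kit, which sequences close to the 3′ end of polyadenylated transcripts, so that a gene's value reflects its 3′ end and not its whole length.

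The authors deposited 1 table per library with a log2 value for each of 23282 gene symbols, written with 3 decimals. Bowtie2, bedtools and the mouse build mm10 are named in the submitters' processing notes, without version or role. The normalization, the annotation and any filter are not given in the sources used here. The scale was read from the values themselves. After conversion with 2 to the power of the value, minus 1, low values fell on whole multiples of a step of 1.056 in WT naive, 0.936 in Egr1 KO naive, 1.08 in WT HDM and 0.939 in Egr1 KO HDM, so the deposited log2 values are log2(x + 1), with x a read number scaled between libraries. Reads per gene were recovered by dividing by the step. Of the genes with up to 200 reads, 98.9%, 95.7%, 98.9% and 98.8% came out whole within 0.1 read, in the same order of libraries (8533, 5534, 9460 and 8651 genes judged). Read numbers above that are approximate, since the 3 decimals limit them.

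The recovered totals were 9610840 reads in WT naive, 9950741 in Egr1 KO naive, 9444989 in WT HDM and 10130471 in Egr1 KO HDM. A count of 0 was taken to allow up to 3 reads of these totals, as counting error would. In Egr1 KO naive this limit may be too low, since 336 genes were at 0 there with 50 or more reads in each other library. Folds given as at least against that library hold only under this limit. Ratios between libraries have exact 95% intervals (Clopper-Pearson, conditional on the summed reads). A ratio against a library at 0 reads is given as at least N-fold, computed against 3 reads per library. Libraries without molecular identifiers count reads and not molecules, so these intervals and limits cover counting error only, not the spread between animals.

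Scripts in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1) and R 4.3.3 (limma 3.58.1) did the rest. Symbols on more than 1 line of the tables were left out (35 symbols on 79 lines). A gene was called measured when its mean over the 4 libraries lay above the median of all genes, 5.10 on the log2 scale, which left 11624 genes. Of all symbols, 5623 stood at 0 in every library. The 4 comparisons were HDM against naive in WT skin, HDM against naive in KO skin, KO against WT in naive skin and KO against WT in HDM skin. With 1 library per group they have no replicate check and no p-value: each gene has the difference of its deposited log2 values, and a gene past the size rule differs by 2-fold or more, a log2 difference of at least 1. Such a difference compares those libraries, not the conditions.

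Gene lists were described by the median log2 difference of their measured members, by its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, and by the number of members past the size rule. A list needed at least 3 measured members, and its median was called outside the random lists when it left their central 95%. Of 32 lists, 29 could be described. The lists of B cell and plasma cell markers (0 measured members), eosinophil markers (1) and sex-linked transcripts (2) were too small. A list's percentile describes these libraries and is not a test across animals. Some lists share members, so their medians are not independent. Il4ra and Il33, for example, are in the itch and the type 2 lists, and Klk6 is in the wound keratinocyte and the desquamation lists.

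As a secondary result, an additive model with a treatment and a genotype term was fitted to all 4 libraries with limma, with an intensity trend and Benjamini-Hochberg adjusted p under 0.05 as the threshold. It has 1 residual degree of freedom per gene, and a gene's own error is the departure from additivity. It thus assumes that both genotypes respond alike apart from the spread between libraries. Limma moderates this error towards that of other genes of like level, with a prior of 7.93 degrees of freedom (8.93 in all). Most of the error behind a p-value is therefore shared across genes. The gene set test fry was run for each list under the same model. It asks whether a set's genes move, on balance, one way and does not compare the set with other genes. The interaction has no residual degree of freedom, so differences of the HDM response between genotypes were described without a test.

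The groups, comparisons, filters, thresholds, gene lists, the alternatives to most of them and the rule for naming genes were chosen before the data were examined. That rule takes Egr1 and Artn. Per comparison, it takes the 8 largest differences in each direction past the size rule whose higher library lies at or above the 50th percentile of measured genes, without predicted Gm and Rik symbols and small RNA genes. It adds up to 4 members of each list with the largest differences past the size rule, the same 8 per direction for the difference of responses, and the 10 smallest p-values per direction of the additive fit. The design had allowed for read counts or for log2 values; as the tables hold log2 values, the differences of the deposited values were used, and count models were not run. Lists of salivary genes, trunk HOX genes, X-linked genes that escape inactivation and Y-linked genes were added after the data had been seen. They serve the closing section, and 1 salivary list is also given in the results. For the tests on the HOX list and on the other salivary list, whose members mostly lie below the expression filter, a gene was used when it had 10 or more reads in either of the compared libraries. Gene positions are those of GENCODE M21 on mm10.

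Both procedures were tested on simulated data for HDM against naive in WT skin and for the additive HDM effect, on 11625 genes each. The size rule called 50 of 50 genes raised 4-fold, 50 of 50 raised 8-fold, 44 of 45 lowered to 0.25 and 40 of 40 lowered to 0.125. It called 457 of 11440 unchanged genes, with a simulated relative variance of 0.05 between libraries, a value set and not estimated from these data. The additive fit called 49 of 50, 50 of 50, 44 of 45 and 40 of 40 of the same classes and 9 of 11440 unchanged genes. The simulated libraries had no differences of tissue or sex, no lost reads and only additive changes. These calls therefore check the procedures and do not give the error rates of the real comparisons. Counting intervals held the true ratio in 95.8% of cases, and 8 of 200 unchanged lists of 12 members left the central range. The alternatives tried were median centring, quantile normalization, no filter and a stricter filter on low values, other size thresholds, an offset of 16, list means, the removal of some gene classes, limma without trend and without the other factor, and the removal of each library in turn.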

Results

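Gene expression was profiled in the skin of adult mice by 3′ RNA sequencing. The question was how the transcription factor EGR1 bears on the response of the skin to house dust mite (HDM) allergen, a model of atopic dermatitis. The stated interest was the neurotrophic factor artemin (Artn) and the sensory innervation of the epidermis. WT and Egr1 KO mice were either naive, with SDS alone per the labels, or treated with SDS and HDM cream for 3 weeks. Each of the 4 groups held 1 library, with 9444989 to 10130471 reads. The comparisons between single libraries therefore have no replicate error, and their intervals cover counting error alone. The additive fit at the end takes its error from 1 residual degree of freedom per gene and from an error shared across genes. Genes with at least 1 read numbered 15547 in WT naive, 12880 in Egr1 KO naive, 16536 in WT HDM and 16200 in Egr1 KO HDM. In Egr1 KO naive, 336 genes stood at 0 reads that had 50 or more in each other library, against 5, 0 and 4 such genes in WT naive, WT HDM and Egr1 KO HDM. Folds given as at least against Egr1 KO naive take a 0 as up to 3 reads, and would be too large if reads or molecules were lost there.

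Transcripts of the sex chromosomes divided the libraries by treatment. Xist, the RNA that coats the inactive X chromosome, had log2 values of 3.53 in WT naive and 5.26 in Egr1 KO naive against 11.21 and 11.16 in the HDM libraries of WT and KO. The Y-linked helicase gene Ddx3y stood at 10.99 and 11.15 in the naive libraries, with 1925 and 2430 reads, and had 1 read in each HDM library. Every HDM comparison below therefore also compares libraries that differ in sex-linked transcripts. The share of reads on the ribosomal RNA gene Rn45s differed too. It was 1.80% in WT naive and 1.31% in Egr1 KO naive, against 4.81% in WT HDM and 2.65% in Egr1 KO HDM.

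Egr1, an immediate-early zinc finger transcription factor gene (chromosome 18, 34859823 to 34864984, plus strand), was not lower in the libraries labelled Egr1 KO. Its log2 values were 11.02 in WT naive, 11.53 in KO-labelled naive, 10.31 in WT HDM and 11.68 in KO-labelled HDM skin, from 1966, 3159, 1174 and 3494 reads. The KO-labelled library was 1.42-fold higher than WT in naive skin (95% counting interval 1.35 to 1.51) and 2.59-fold higher in HDM skin (2.43 to 2.77). The 3′ tags may lie outside the disrupted part of the gene, which the labels do not describe, so this value checks no label. The libraries are called KO-labelled from here on. With HDM, Egr1 was 1.64-fold lower than naive in WT skin (1.53 to 1.77) and 1.11-fold higher in KO-labelled skin (1.06 to 1.16). Of these 4 differences, the one between genotypes under HDM passed 2-fold.

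Artn, which encodes a ligand of the GDNF family that supports sensory neurons (chromosome 4, 117926162 to 117929763, minus strand), had 0 reads in both naive libraries, 24 in WT HDM and 5 in KO-labelled HDM skin. It was thus at least 8.17-fold higher with HDM in WT skin and at least 1.67-fold higher in KO-labelled skin. Under HDM it was 5.51-fold lower in the KO-labelled library than in WT (2.06 to 18.5). Artn lay below the expression filter in the mean of the 4 libraries, and its values rest on these few reads.

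**Figure D1:**
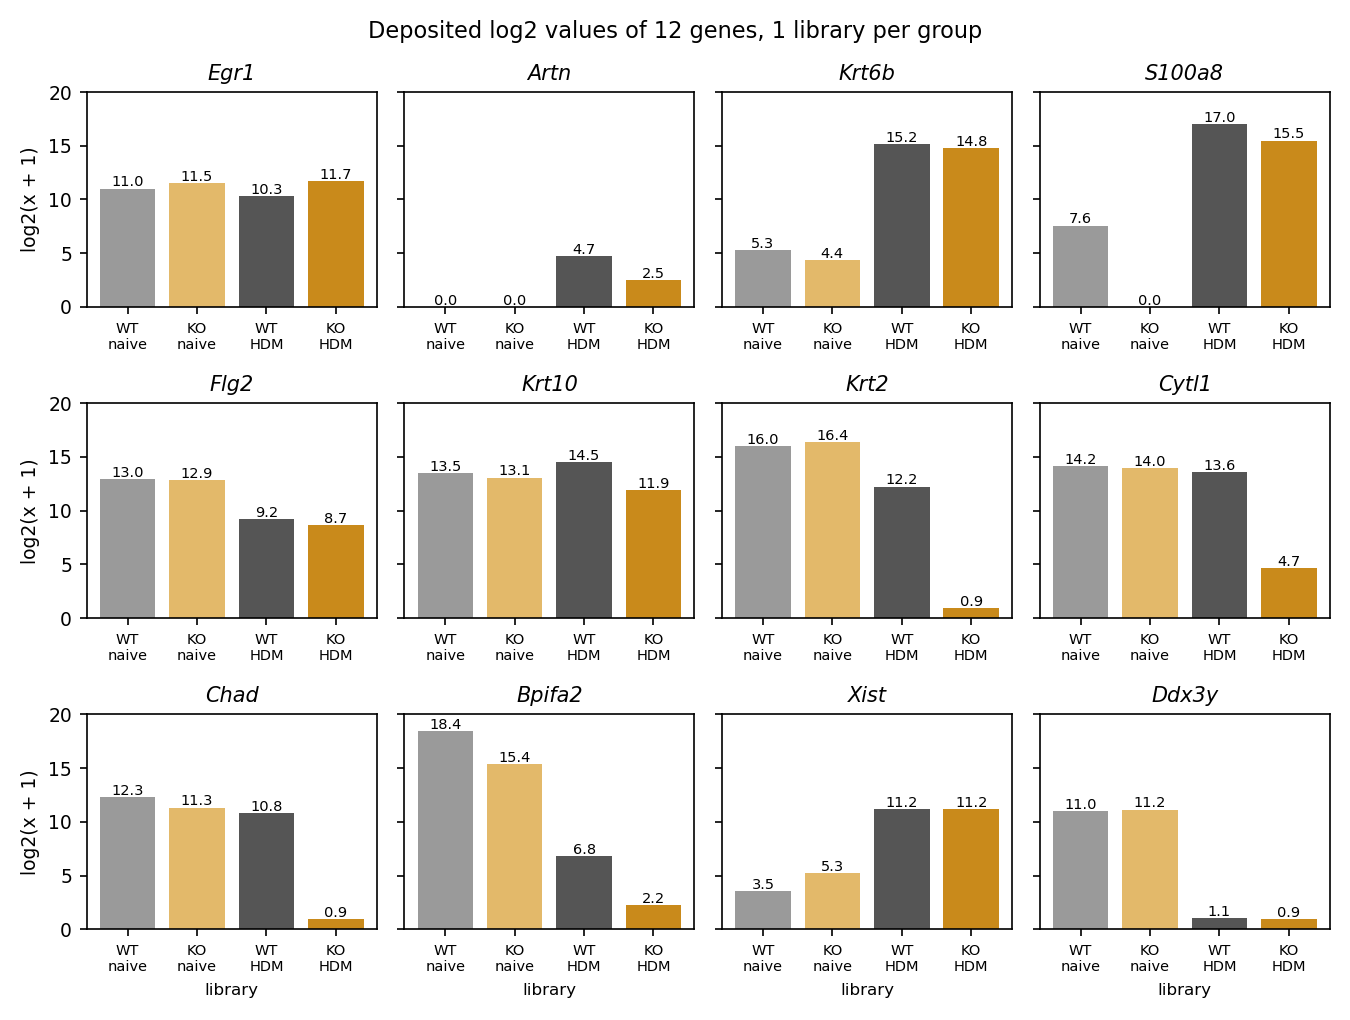
Deposited log2(x + 1) values (vertical axis) of 12 genes in the 4 libraries (bars, 1 library per group, no error bar possible). Egr1 stood between 10.31 and 11.68 in all of them, Krt2 and Chad had 1 read each in the KO-labelled HDM library, and Xist and Ddx3y divided naive from HDM libraries.

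HDM against naive in WT skin asked what the allergen cream did beyond barrier disruption. The keratinocyte genes of wounding and hyperproliferation stood far higher in the HDM library. Krt6b, a keratin of activated epidermis, was 946-fold higher (686 to 1344) and its partner Krt16 542-fold (393 to 769). The cornified envelope genes Sprr2d and Lce3c were 4858-fold (1345 to 40122) and 902-fold higher (414 to 2458). S100a8, which encodes a calprotectin subunit made by neutrophils and stressed keratinocytes, was 693-fold higher (599 to 807), with 121610 reads against 179. The genes lowest against naive skin were secretory genes known from salivary and lacrimal glands. Among them were Pip with 19995 reads in naive and 1 in HDM skin, Smr3a with 248931 and 47, and Bpifa2 with 336299 and 104. A list of 11 such genes, chosen after their values were seen, had a median of -10.93 in WT skin and of -8.40 in KO-labelled skin, or -6.46 there with genes at 0 set to 3 reads. In all, 1685 of 11624 measured genes were higher and 1483 lower by 2-fold or more, and 8456 differed by less. Sprr2, Lce3 and keratin-associated protein genes have near-identical copies, so their single values are uncertain where reads could be shared.

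Of 27 measured wound and hyperproliferation genes, 24 were higher with HDM in WT skin and 0 lower, with a list median of 6.18 on the log2 scale. Among 26 cell cycle genes 17 were higher and 0 lower (median 1.77), with the mitotic kinase gene Plk1 37.4-fold higher (25.9 to 56.2), Ube2c 17.5-fold (13.9 to 22.3) and Birc5 7.13-fold (6.22 to 8.20). The 16 proteases and inhibitors of desquamation, the shedding of the outer layer, had a median of 1.62, with 11 higher and 2 lower. The kallikrein gene Klk6 was 429-fold higher (245 to 830) and the protease inhibitor gene Slpi 21.6-fold (14.8 to 32.8). Epidermal barrier genes went both ways, 15 of 41 higher and 14 lower, with a median of 0.345. Repetin (Rptn) was 261-fold higher (177 to 403) and Krt1 24.8-fold (23.2 to 26.5). The filaggrin relative Flg2 was 13.6-fold lower (12.5 to 14.9) and Krt2 13.3-fold lower (12.9 to 13.7). Cartilage markers were lower in this HDM library as well (median -1.50). A difference of sampled tissue between both libraries therefore cannot be told apart from HDM for such genes. The barrier median lay at percentile 98.3 of the random lists and was -0.005 under a stricter expression filter.

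Type 17 and neutrophil-attracting genes were higher as well in WT skin with HDM. Of 8 measured, 7 were higher (median 3.78), among them S100a9, 198-fold (178 to 221), the antimicrobial peptide gene Defb14, 16.4-fold (13.0 to 21.0), and Lcn2, 15.0-fold (12.3 to 18.4). Neutrophil markers had a median of 2.72 (5 of 7 higher, 1 lower), with the chemokine receptor gene Cxcr2 12.5-fold (7.51 to 22.3) and Il1b 6.63-fold higher (5.31 to 8.38). S100a8, S100a9 and Il1b belong to both lists. Among 11 itch mediators and receptors 7 were higher and 1 lower (median 1.52). They included the interleukin 4 receptor gene Il4ra, 7.23-fold (5.83 to 9.06), the alarmin gene Il33, 6.03-fold (5.01 to 7.31), and Osmr, 3.75-fold (2.79 to 5.10). Type 2 cytokines and chemokines had 5 of 11 higher and 3 lower (median 0.70); Ccl8 was 12.1-fold higher (10.8 to 13.6), and Retnla 7.70-fold lower (5.71 to 10.6). Macrophage and monocyte markers (12 of 23 higher, 1 lower, median 1.09), endothelial markers (3 of 13 higher, 1 lower, 0.72) and erythrocyte genes (3 of 8 higher, 0 lower, 0.83) also lay above the random lists. The chemokine gene Pf4 was 5.12-fold (4.27 to 6.16) and the monocyte receptor gene Ccr2 3.86-fold higher (3.35 to 4.45).

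Hair shaft and inner root sheath genes, which mark growing follicles, had 28 of 30 members higher and 0 lower in WT skin with HDM (median 5.25). The root sheath keratin gene Krt71 was 358-fold (200 to 718) and the hair keratin gene Krt31 218-fold higher (99.8 to 594). Lower lists included Schwann cell markers, with 10 of 11 lower (median -2.24). The neurotrophin receptor gene Ngfr was 13.3-fold lower (10.6 to 16.9). Sebaceous gland markers had 9 of 14 lower and 0 higher (median -1.55), with the desaturase gene Scd1 12.9-fold lower (12.6 to 13.3). Cartilage markers had 8 of 11 lower and 0 higher (-1.50), with Col9a1 8.92-fold lower (6.37 to 12.8). Adipocyte markers had 5 of 15 lower and 0 higher (-0.88), with Retn 4.04-fold lower (3.47 to 4.72). T cell and innate lymphoid markers had 3 of 6 lower and 0 higher (-0.83), with Rora 3.74-fold lower (3.56 to 3.93). The T cell median was 0.31 without the expression filter.

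The remaining lists stayed within the range of random lists in WT skin. Sensory neuron transcripts had a median of -0.43 (2 of 6 lower, 0 higher; 0.50 over 22 without the filter), neurotrophins and GDNF-family ligands -0.69 (1 of 5 higher, 1 lower) and axon guidance ligands -0.05 (2 of 19 in each direction). Single members were far from 0: the growth cone gene Gap43 was 2.63-fold lower (1.87 to 3.75), Bdnf 3.77-fold lower (2.65 to 5.48), Vegfa 3.15-fold higher (2.74 to 3.62), and the repulsive guidance gene Sema3d 19.5-fold lower (14.8 to 26.3). Medians were -0.40 for interferon-stimulated genes (2 of 16 higher, 5 lower) and -0.59 for mast cell and basophil markers (1 of 9 higher, 3 lower). They were -0.76 for melanocyte markers (0 of 5 higher, 1 lower) and -0.09 for dendritic and Langerhans cell markers (1 of 11 higher, 2 lower). Fibroblast and matrix genes stood at -0.19 (5 of 25 higher, 8 lower) and skeletal muscle genes at -0.29 (1 of 25 higher, 5 lower). Medians were -0.02 for basal keratinocyte markers (3 of 13 higher, 5 lower) and 0.21 for heat shock and stress genes (4 of 17 higher, 1 lower). Collagen gene Col1a1 was 5.46-fold lower (5.37 to 5.56), while Timp1, an inhibitor of matrix metalloproteases, was 11.4-fold higher (8.60 to 15.3). Immediate early and EGR genes had a median of 0.22 and a mean of -0.10, with 5 of 29 in each direction; Fosb was 117-fold lower (45.3 to 431) and Socs3 8.57-fold higher (7.51 to 9.80).

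**Figure D2:**
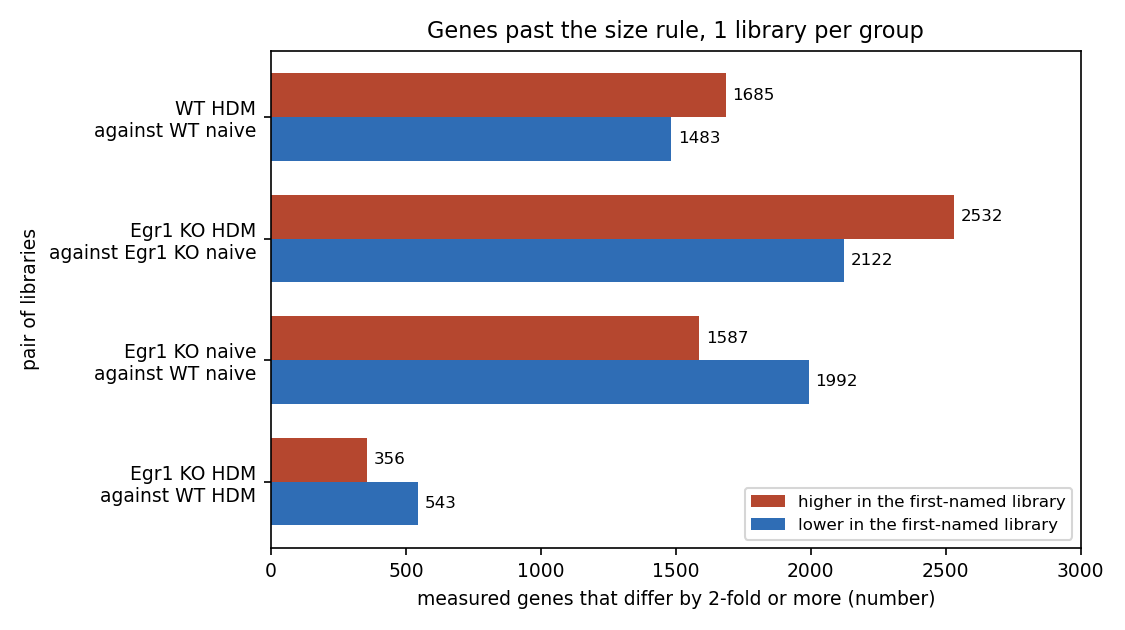
Number of measured genes (horizontal axis) that differed by 2-fold or more in each of the 4 pairs of libraries, higher and lower in the first-named library. KO-labelled and WT libraries differed least under HDM, with 356 genes higher and 543 lower, and HDM and naive most in KO-labelled skin, with 2532 and 2122.

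HDM against naive in KO-labelled skin asked for the same response in mice labelled as lacking Egr1. Wound keratinocyte genes and type 17 and neutrophil-attracting genes were again higher, with Krt6b at 1439-fold (941 to 2326). S100a8, S100a9, the stefin gene Stfa1 and Sprr2d, all at 0 reads in the naive library, were at least 16289-fold, 10927-fold, 3647-fold and 1067-fold higher. The hair genes Krt71 and Krt85 were at least 3287-fold and 1128-fold higher. Krt2, a keratin of the upper epidermis of ear, tail and sole skin in mice, had 93557 reads in naive and 1 in HDM skin, and the cartilage gene Chad 2765 against 1. Smr3a was at least 9179-fold lower, and Bpifa2 had 44935 reads against 4. In all, 2532 measured genes were higher and 2122 lower; 240 of the higher genes had 0 reads in the naive library.

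Of the wound and hyperproliferation genes 25 of 27 were higher and 1 lower in KO-labelled skin with HDM (median 7.41, or 6.88 with genes at 0 set to 3 reads). Type 17 and neutrophil-attracting genes had 6 of 8 higher and 0 lower (7.67, or 6.71 with such genes at 3 reads); Il1b was at least 333-fold and the chemokine gene Cxcl2 at least 104-fold higher. Neutrophil markers had a median of 5.35 (4 of 7 higher, 1 lower), which was -0.10 without the genes at 0 reads in the naive library. Cell cycle genes (19 of 26 higher, 0 lower, median 1.71), hair genes (28 of 30 higher, 0 lower, 6.14), proteases and inhibitors of desquamation (8 of 16 higher, 1 lower, 1.01) and heat shock and stress genes (7 of 17 higher, 1 lower, 0.81) also lay above the random lists. Klk6 was 41.5-fold higher (33.6 to 51.8), the matriptase gene St14 11.2-fold (7.80 to 16.5) and the chaperone gene Hsph1 4.15-fold (3.46 to 4.99). Epidermal barrier genes lay below the random lists, at percentile 0.875, with 18 of 41 lower and 10 higher (median -0.33). The late envelope gene Lce1m was 109-fold lower (76.7 to 161), and Rptn at least 1060-fold higher.

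Most cartilage markers, fibroblast and matrix genes, and dendritic and Langerhans cell markers were lower in KO-labelled skin with HDM. Cartilage markers had 10 of 11 lower and 0 higher (median -5.90), with Cytl1 656-fold lower (448 to 1005). Fibroblast and matrix genes had 15 of 25 lower and 1 higher (-1.27), with elastin (Eln) 15.8-fold (14.5 to 17.3) and Col3a1 11.1-fold lower (10.9 to 11.4). Dendritic and Langerhans cell markers had 8 of 11 lower and 1 higher (-2.27). The lectin gene Mgl2 was 12.3-fold (8.56 to 18.4) and the MHC class II chaperone gene Cd74 6.78-fold lower (6.51 to 7.06). Of the sensory neuron transcripts above the filter, 4 of 6 were lower and 0 higher (-1.71), with Stmn2, a tubulin-binding gene of growing axons, 6.25-fold (5.06 to 7.79) and the GDNF-family receptor gene Ret 4.36-fold lower (3.20 to 6.03). Over 22 members without the filter the median was 0, and some went the other way, such as Nppb with 0 reads in naive and 307 in HDM skin and Tubb3 with 1 and 249. Schwann cell markers had 5 of 11 lower and 0 higher (-0.96), with S100b, which is also expressed in cartilage, 99.8-fold lower (80.2 to 126). Adipocyte markers had 6 of 15 lower and 1 higher (-0.81), with Adipoq 4.79-fold lower (4.45 to 5.16). Skeletal muscle genes had 7 of 25 lower and 1 higher (-0.44), with Casq1 3.27-fold lower (2.98 to 3.59).

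In KO-labelled skin, medians within the range of random lists were 0.68 for itch mediators and receptors (5 of 11 higher, 3 lower) and 0.22 for type 2 genes (3 of 11 in each direction). Ccl8 was 11.5-fold higher (10.4 to 12.7), the substance P receptor gene Tacr1 3.92-fold higher (2.64 to 5.97) and Retnla 12.3-fold lower (10.4 to 14.8). Macrophage and monocyte markers had a median of -0.20 (0 of 23 higher, 9 lower), T cell markers -0.77 (0 of 6 higher, 3 lower), mast cell markers -0.55 (3 of 9 higher, 4 lower) and interferon-stimulated genes -0.45 (4 of 16 in each direction). Sebaceous markers (0.08), basal keratinocyte markers (0.66), axon guidance ligands (0.47), neurotrophins (-0.23, with a mean of 0.06), melanocyte markers (0.24), endothelial markers (-0.31), erythrocyte genes (-0.54) and immediate early genes (0.17) completed the set. Members with large differences were Krt14, 6.90-fold higher (6.72 to 7.09), Vegfa, 8.14-fold higher (6.48 to 10.3), and Sema3a, 14.1-fold lower (9.48 to 21.9).

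**Figure D3:**
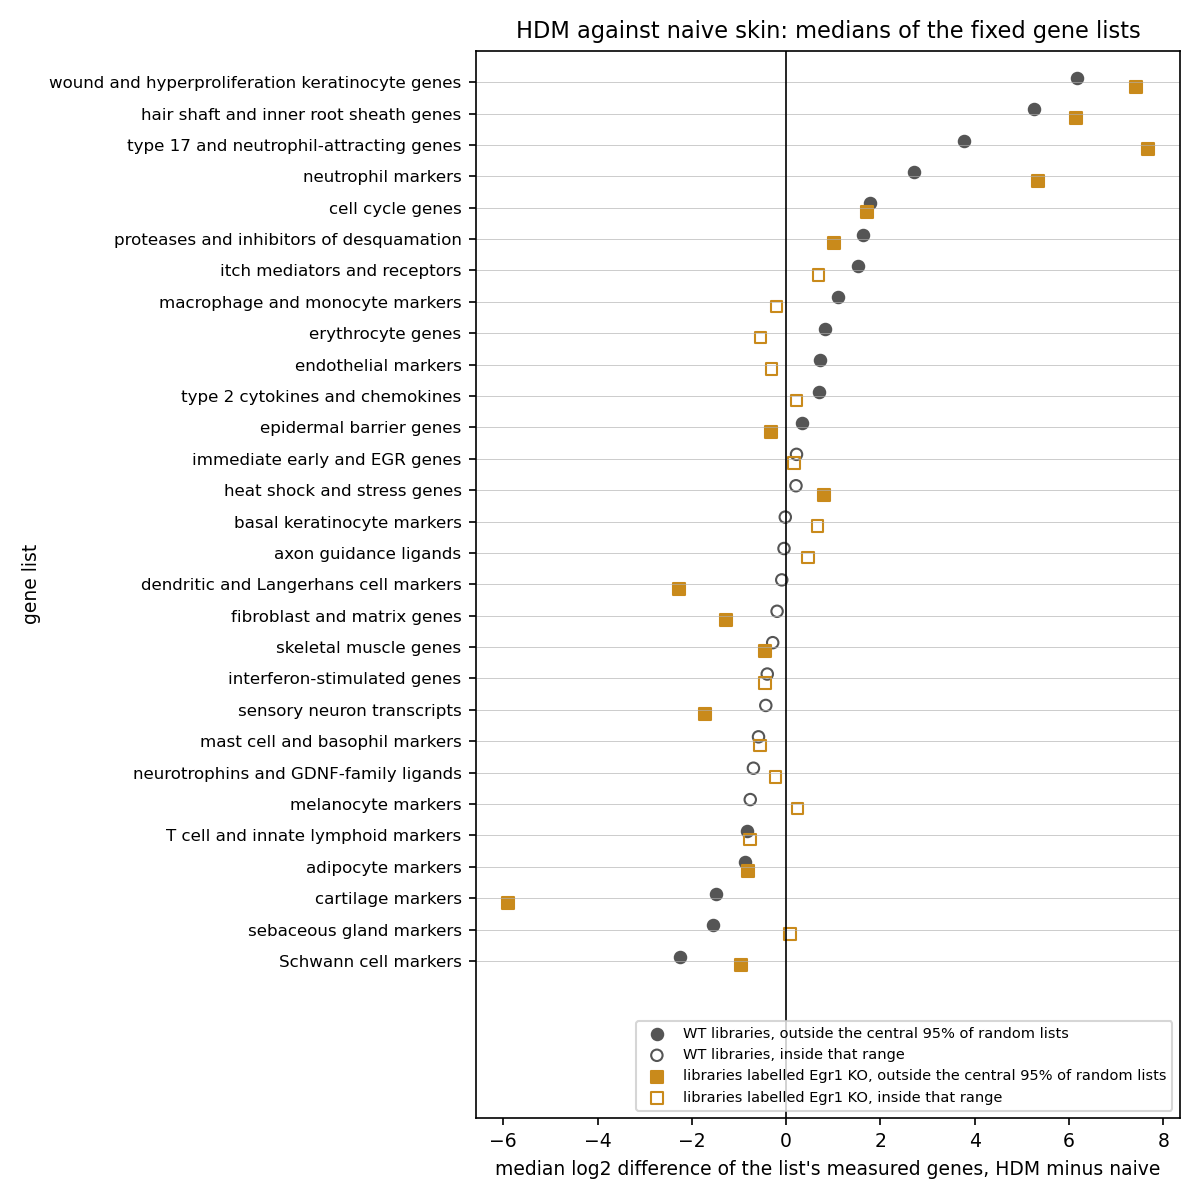
Median log2 difference of HDM minus naive (horizontal axis) for each of 29 gene lists (vertical axis), in WT libraries (circles) and KO-labelled libraries (squares); filled symbols lie outside the central 95% of random lists. Wound keratinocyte genes stood at 6.18 and 7.41, Schwann cell markers at -2.24 and -0.96, and cartilage markers at -1.50 and -5.90.

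KO-labelled against WT naive skin asked for the effect of genotype before HDM. The adipocyte, matrix and macrophage lists lay above the random lists in the KO-labelled library, with a minority of their members higher by 2-fold or more. The leptin gene Lep was 12.2-fold higher (8.42 to 18.3), the matrix gene tenascin C (Tnc) 7.29-fold (6.57 to 8.09) and the mannose receptor gene Mrc1 of tissue macrophages 5.39-fold (4.88 to 5.97). The largest differences upward were in Rufy4, 74.2-fold (38.9 to 163), major urinary protein genes such as Mup2, 32.3-fold (23.1 to 46.6), and Crtc2, 23.6-fold (13.3 to 46.2). The Mup genes are near-identical copies, so their single values are uncertain. Downward, the lactoperoxidase gene Lpo was at least 290-fold, the transcription factor gene Gtf2e2 at least 173-fold, the cilium gene Ift52 at least 151-fold and S100a9 at least 122-fold lower. Each had 0 reads in the KO-labelled library. The 11 secretory genes chosen after their values were seen were lower as well, 11 of 11 with a median of -3.61, among them Bpifa2 with 44935 reads against 336299. In all, 1587 measured genes were higher and 1992 lower, and 238 of the lower genes were at 0 reads there. Rescaled without mitochondrial, keratin-associated protein and muscle genes, the balance turned, with 1881 higher and 1705 lower.

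In naive skin, adipocyte markers had 7 of 15 higher and 1 lower in the KO-labelled library (median 0.85), fibroblast and matrix genes 10 of 25 higher and 0 lower (0.71), and macrophage and monocyte markers 9 of 23 higher and 0 lower (0.88). Dendritic and Langerhans cell markers had 2 of 11 higher and 0 lower (0.87), with Cd86 4.38-fold higher (3.20 to 6.10), and skeletal muscle genes 2 of 25 higher and 0 lower (0.50). Fabp4 was 4.38-fold (4.26 to 4.51), Col3a1 3.13-fold (3.09 to 3.18) and Pf4 4.41-fold higher (3.68 to 5.31). Type 17 and neutrophil-attracting genes lay below the random lists (median -4.93, or -3.96 with genes at 0 set to 3 reads; 5 of 8 lower, 1 higher). So did neutrophil markers (-2.25; 4 of 7 lower, 1 higher) and wound keratinocyte genes (-1.42; 16 of 27 lower, 2 higher). Without the genes at 0 reads in the KO-labelled naive library, the type 17 median was 0.073. The serpin gene Serpinb3a was 226-fold lower (76.8 to 1097) and the stefin-like gene BC100530 25.1-fold lower (20.3 to 31.4). Sebaceous gland markers (6 of 14 lower, 0 higher, -0.57) and basal keratinocyte markers (4 of 13 lower, 0 higher, -0.46) were the other lists below the random range, with Elovl3 3.65-fold (3.41 to 3.91) and Krt14 2.15-fold lower (2.08 to 2.21).

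The other lists of naive skin lay within the random range. Medians were 0.39 for type 2 genes and 0.32 for itch genes, with 4 of 11 higher and 0 lower in each. They were 0.08 for sensory neuron transcripts (3 of 6 in each direction), -0.39 for Schwann cell markers (0 of 11 higher, 3 lower) and -0.19 for cartilage markers (0 of 11 higher, 2 lower). Among their members, Retnla was 4.02-fold higher (3.60 to 4.50), the eotaxin gene Ccl11 3.73-fold (2.85 to 4.96), Il4ra 2.48-fold (1.96 to 3.17), Ret 5.07-fold (3.59 to 7.32) and Uchl1 4.03-fold (3.17 to 5.17). The Schwann cell factor gene Sox10 was 4.18-fold lower (3.42 to 5.15). Neurotrophins had a median of -0.13 and axon guidance ligands of -0.14. Sema3a was 13.6-fold higher (8.99 to 21.5), Bdnf 5.43-fold lower (3.69 to 8.22) and Vegfa 3.65-fold lower (2.85 to 4.72). Immediate early and EGR genes had a median of -0.33 (3 of 29 higher, 6 lower), with Atf3 14.1-fold (8.36 to 25.8) and Egr2, a close relative of Egr1, 3.20-fold lower (2.64 to 3.90). Barrier genes stood at -0.18 (2 of 41 higher, 9 lower), cell cycle genes at -0.12 (6 of 26 in each direction) and hair genes at 0.15 (8 of 30 higher, 12 lower). Heat shock genes (0.08), erythrocyte genes (0.23), endothelial markers (0.45), proteases and inhibitors of desquamation (-0.24), interferon-stimulated genes (-0.26), melanocyte (-0.20), mast cell (-0.36) and T cell markers (-0.39) were within the range as well.

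KO-labelled against WT skin under HDM asked how the HDM-treated skin differed with genotype. A majority of epidermal barrier genes were lower in the KO-labelled library. Among single epidermal genes, the suprabasal keratin gene Krt10 was 6.10-fold lower (5.90 to 6.31), Lce3c 5.61-fold (5.25 to 5.99) and the protease inhibitor gene Serpinb12 4.30-fold (3.79 to 4.90). Krt2 had 1 read against 4493. Cartilage genes were lower too. Chad had 1 read against 1651, Cytl1 was 513-fold (350 to 785) and the cartilage proteoglycan gene Acan 27.5-fold lower (19.2 to 40.7). Most hair and sebaceous genes were higher, with the trichohyalin gene Tchh 3.45-fold (3.35 to 3.55) and Elovl3 4.51-fold (4.19 to 4.85). Of single genes, the pigment genes Tyrp1 and Dct were 5.80-fold (4.39 to 7.78) and 4.72-fold higher (4.23 to 5.28), and the immediate early gene Fos was 6.99-fold higher (5.60 to 8.81). These libraries were the closest pair, with 356 of 11624 measured genes higher, 543 lower and 92.3% within 2-fold. The sex-linked transcripts Xist and Ddx3y were at like levels in both. A sample of another body site, weighed in the closing section, would bear on every list of this comparison and of HDM against naive in KO-labelled skin. Genotype and site cannot be told apart here.

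Under HDM, epidermal barrier genes had 24 of 41 lower and 1 higher in the KO-labelled library (median -1.37), wound keratinocyte genes 12 of 27 lower and 0 higher (-0.86), and proteases and inhibitors of desquamation 4 of 16 lower and 1 higher (-0.65). Type 17 and neutrophil-attracting genes had 4 of 8 lower and 1 higher (-0.76). S100a8 was 2.87-fold lower (2.84 to 2.90), the interleukin 36 gamma gene, listed as Il1f9, 2.98-fold lower (2.61 to 3.41), and Cxcl2 2.46-fold higher (1.98 to 3.09). Neutrophil markers stood at -0.49 (2 of 7 lower, 0 higher), within the random range. Macrophage and monocyte markers (5 of 23 lower, 0 higher, -0.73), dendritic and Langerhans cell markers (4 of 11 lower, 0 higher, -0.68), erythrocyte genes (4 of 8 lower, 0 higher, -0.97) and fibroblast and matrix genes (4 of 25 lower, 1 higher, -0.34) lay below it. Ccr2 was 3.27-fold (2.88 to 3.72), the MHC class II gene H2-Eb1 3.22-fold (2.96 to 3.51) and Eln 3.23-fold lower (2.92 to 3.56). Of the sensory neuron transcripts above the filter, 2 of 6 were lower and 0 higher (-0.73, or -0.31 over 22 without the filter), Stmn2 by 3.00-fold (2.38 to 3.81) and Gap43 by 2.70-fold (1.57 to 4.81). Below the filter, Nppb had 307 reads against 35 in WT, Calca 40 against 7, and the artemin receptor gene Gfra3 31 against 2. Cartilage markers had 8 of 11 lower and 0 higher (-3.91, or -3.46 with genes at 0 set to 3 reads).

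Higher lists in the KO-labelled HDM library were hair genes (18 of 30 higher, 0 lower, median 1.15), sebaceous gland markers (9 of 14 higher, 1 lower, 1.21), adipocyte markers (7 of 15 higher, 0 lower, 0.95), and melanocyte markers (2 of 5 higher, 0 lower, 0.90). Basal keratinocyte markers (2 of 13 higher, 0 lower, 0.52), skeletal muscle genes (1 of 25 higher, 0 lower, 0.35) and heat shock genes (1 of 17 higher, 0 lower, 0.32) followed. Lep was 3.55-fold (2.33 to 5.57), the laminin gene Lama3 3.19-fold (2.63 to 3.90) and the fast muscle gene Mybpc2 6.06-fold higher (4.74 to 7.84). Lists within the random range were cell cycle genes (-0.01, 0 of 26 higher and 1 lower), type 2 genes (-0.09), itch genes (-0.27), neurotrophins (-0.47, 0 of 5 past 2-fold) and axon guidance ligands (-0.04). Others were interferon-stimulated genes (0.28), mast cell markers (-0.10), T cell markers (0.04), endothelial markers (-0.05) and immediate early and EGR genes (0.01). Of the latter, 5 of 29 were higher and 2 lower, with Fosb 26.8-fold (10.2 to 99.9) and Nr4a1 4.09-fold higher (3.08 to 5.51) and Ctgf 3.87-fold lower (3.67 to 4.08). Schwann cell markers had a median of 0.24 and a mean of -0.01.

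The HDM responses of both genotypes were then set side by side, without a test. Across the 11624 measured genes, which are not independent replicates, the responses share no library and correlated with r = 0.519 (Spearman 0.455). Genes higher in both numbered 822, where independent lists of these sizes would share 367, and genes lower in both 783, where they would share 271. Opposite directions past 2-fold were seen in 205 genes, fewer than in either shared direction. Of the 1685 genes higher with HDM in WT skin, 1453 (86.2%) lay within 2-fold between the HDM libraries. In the KO-labelled one 194 were lower and 38 higher, against 78.7 and 51.6 for independent lists. Of the 1483 genes lower with HDM in WT skin, 189 were higher and 132 lower there, against 45.4 and 69.3. HDM in WT skin and genotype under HDM both use the WT HDM library. Their covariance across genes was -0.14, and it was -0.01 in simulated libraries that differ by counting error alone and not by the spread between animals. As correlations these were -0.18 and -0.51. Part of the excess among the 194 and the 189 genes may come from the shared library. The excess among the 132 genes has the direction opposite to that.

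The difference of the HDM responses, KO-labelled minus WT, was positive for type 17 genes (median 4.76), sebaceous markers (1.90), neutrophil markers (1.78), melanocyte markers (1.56), wound keratinocyte genes (1.14), hair genes (1.03), basal keratinocyte markers (1.01) and immediate early genes (0.59), each above random lists. It was negative for cartilage markers (-3.59), dendritic and Langerhans cell markers (-1.65), macrophage and monocyte markers (-1.57), erythrocyte genes (-1.57), itch genes (-1.39), type 2 genes (-1.03), barrier genes (-0.85) and fibroblast and matrix genes (-0.83), each below them. The 8 genes with the largest positive difference, among them Gtf2e2 (9.57), the hair follicle stem cell factor gene Lhx2 (9.11) and Ift52 (8.92), were all at 0 reads in KO-labelled naive skin. Without the genes at 0 there, the type 17 difference was -0.58 and the neutrophil one -0.40, and with an offset of 16 the wound keratinocyte difference was -0.34. The largest negative differences were in Krt2 (-11.75), Rufy4 (-10.89), Chad (-8.89) and Cytl1 (-8.76). Of these, Krt2, Chad and Cytl1 had 1, 1 and 26 reads in the KO-labelled HDM library. Were that sample from another body site, as weighed in the closing section, this would bear on these differences and on the lists above. Genotype and site cannot be told apart in them.

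An additive fit over the 4 libraries asked which genes moved with HDM in both genotypes alike. Singly, 24 of 27 wound keratinocyte and 21 of 30 hair genes rose by limma, while as sets neither passed limma's fry (adjusted p = 0.266 and adjusted p = 0.290). By limma, the fit gave Krt6b a log2 change of 10.14 (SE 0.353, adjusted p = 2.43e-06), the root sheath keratin gene Krt25 6.89 (SE 0.337, adjusted p = 1.91e-05), the gap junction gene Gjb2 6.70 (SE 0.408, adjusted p = 9.23e-05) and Tchh 6.04 (SE 0.369, adjusted p = 9.23e-05). Flg2 fell by 3.96 (SE 0.320, adjusted p = 0.000381) and the progestin receptor gene Paqr7 by 4.78 (SE 0.425, adjusted p = 0.000591), behind the secretory genes Bpifa2 and Smr3a, which fell by 12.37 and 13.48. In all, 262 genes rose and 216 fell with HDM at adjusted p under 0.05, but without the intensity trend limma called 4 higher and 11 lower. For genotype, limma called 0 genes (382 genes at an unadjusted p under 0.05). The smallest adjusted p values for genotype were 0.0688 for Bpifa2 and 0.0791 for Smr3a.

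Of the fixed lists in the additive fit, 6 of 26 cell cycle genes (15 adjusted over the list alone) and 5 of 8 type 17 genes (8) rose; by that adjustment 25 wound keratinocyte and 28 hair genes did. Barrier genes had 5 rising and 12 falling (13 and 16 adjusted over the list alone), fibroblast and matrix genes 0 and 7 (1 and 11), Schwann cell markers 0 and 3 (0 and 9) and cartilage markers 0 and 4 (0 and 9). By limma's fry, 0 of 29 lists passed for HDM, with a smallest adjusted p of 0.0950 and an adjusted p of 0.266 for wound keratinocyte genes, and 5 lists had an unadjusted p under 0.05. For genotype 0 lists passed, with a smallest adjusted p of 0.910 and 1 list at an unadjusted p under 0.05. Fits that left out 1 library had the treatment term alone, which on all 4 libraries gave 28 rising and 14 falling genes. With that term, 2221 genes rose and 1506 fell without WT naive, and 579 and 336 without KO-labelled naive. Without WT HDM 44 rose and 115 fell, and without KO-labelled HDM 81 and 89, where the lone library of a level is assumed to vary like the others.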

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

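The results of this part were singled out because the HDM response went one way in WT and the other way in KO-labelled skin; with 1 library per group the difference was not tested in any of them, and no test was chosen after the results were seen. Epidermal barrier genes had a median HDM response of 0.345 (log2) in WT and of -0.327 in KO-labelled skin, with members in both directions in each. Under the stricter expression filter the WT median was -0.005, so its direction depends on the filter.

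Among the genes tabulated for the comparisons as largest differences or list members, and those with the largest difference of responses, 15 had opposite responses past the size rule. Rufy4, a gene of dendritic cell autophagy, had a log2 response of 5.59 in WT and of -5.31 in KO-labelled skin, with 9, 754, 469 and 18 reads in WT naive, KO-labelled naive, WT HDM and KO-labelled HDM. Clstn3, a synaptic and adipocyte membrane protein gene, had -2.83 and 2.65. Crtc2, a coactivator of CREB, had 2.82 and -1.85. The transcription factor gene Sim2 had 1.03 and -6.05, and Mup14, a member of a family of near-identical genes, 1.03 and -2.36. Sema3a, a repulsive axon guidance gene, had 1.71 and -3.77, on 24, 368, 79 and 26 reads in the same order. Of epidermal and matrix genes, Tgm1 had 2.64 and -1.11, Krt10 1.01 and -1.17, Tnc 1.17 and -1.27, and Lama3 -1.15 and 2.66. The macrophage and platelet genes Mrc1 and Pf4 had 1.87 and -1.02, and 2.35 and -1.12. The endothelial chemokine receptor gene Ackr1 had 1.86 and -1.56, the sebaceous gene Elovl3 -1.99 and 2.05, and the stress gene Atf3 -2.04 and 2.53. None of these differences was tested, and no explanation was weighed for them.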

How the results depend on the processing

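An offset of 16, the restriction to genes whose counting interval excludes 1, the removal of genes at 0 reads in KO-labelled naive skin and the removal of salivary, cartilage, muscle and hair lists with the genes of X and Y were chosen after the data were seen; the other settings were not. For 13 counts and correlations, 85 alternative values stayed within a margin (1.5 times for a count) and 52 moved. For 145 list medians, 1041 stayed, 96 moved and 8 changed sign, and for 429 differences of named genes 1458 stayed, 257 moved and 1 changed sign. The scalings moved the share of higher among differing genes by up to 9.95 points, for genotype under HDM rescaled without mitochondrial, keratin-associated protein and muscle genes (437 higher, 445 lower). The balance turned for genotype in naive skin (1881 and 1705 with that rescaling, 1758 and 1748 after quantile normalization), for HDM in WT skin (1529 and 1654 after median centring, 1657 and 1755 after quantile normalization) and for HDM in KO-labelled skin (2213 and 2368 after quantile normalization). Limits set by depth are those of counting: most named differences exceed them, whereas Artn and other genes of few reads do not allow finer statements. The spread between animals is unknown. No analysis paired by animal was possible because each group holds 1 library. The additive fit compared HDM with naive within genotype. Count models were not run, since the tables hold log2 values, and of other offsets only 16 was tried.

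Without the expression filter, more genes enter. HDM then gave 3981 higher and 3041 lower in WT skin, and 5948 and 2874 in KO-labelled skin. Genotype gave 2241 higher and 5079 lower in naive skin, and 1592 and 2291 under HDM. With a filter at the 75th percentile, fewer do: 691 and 566, 989 and 731, 415 and 574, and 95 and 154 in the order of the 4 comparisons. A threshold of 1.5-fold gave 3069 and 2758 for HDM in WT skin, 3296 lower in KO-labelled skin, 2875 and 3183 for genotype in naive skin and 1142 and 1423 under HDM. A threshold of 4-fold gave 416 and 317, 1032 and 659, 306 and 788, and 26 and 106. Larger or smaller totals follow from the construction of these settings. The share of higher among differing genes moved too. Without the filter it moved by 3.51, 13.0, -13.7 and 1.40 points in the order of the 4 comparisons. At 4-fold it moved by 3.56, 6.62, -16.4 and -19.9 points. The cause of these moves was not tested. The correlation of the HDM responses was 0.372 without the filter, 0.659 with the stricter one, 0.565 with the offset of 16, 0.482 without the other-tissue lists and the genes of X and Y, and 0.455 by Spearman; the cause was not tested.

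For the additive HDM effect, limma without trend called 4 genes higher and 11 lower, a fit without the genotype term 28 and 14, and no filter 777 and 516. Leaving out 1 library, with the same treatment term alone, gave 44 to 2221 higher and 89 to 1506 lower, with the extremes from leaving out WT HDM, KO-labelled HDM and WT naive. Without the other-tissue lists and the genes of X and Y, 218 rose and 184 fell. For genotype, median centring called 2 genes lower, no filter 10 higher and 58 lower, and leaving out 1 library 0 to 1 lower, 1 without KO-labelled naive. The cause was not tested.

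Some medians changed sign. Without the genes at 0 reads in KO-labelled naive skin, the type 17 median was 0.073 for genotype in naive skin and -0.58 for the difference of responses, and the neutrophil median -0.10 for HDM in KO-labelled skin and -0.40 for the difference of responses; the genes left out set these medians. The neutrophil difference was -0.19 after quantile normalization, the wound keratinocyte difference -0.34 with an offset of 16, the barrier median for HDM in WT skin -0.005 under the stricter filter, and the T cell median 0.31 without a filter. Cxcr2, on 3 and 16 reads, went to 1.09 for genotype in naive skin after quantile normalization. The cause was not tested.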

Other observations

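Among the tests of this part, those of cartilage genes against loss of Egr1, of depth and of silencing by loss of Egr1 were chosen only after the result was seen, as were the genes of the next paragraph.

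Several cytokine and antimicrobial genes lay below the expression filter, most with few or 0 reads in naive skin. The type 17 cytokine genes Il17a and Il17f had 0 reads in both naive libraries, 72 and 113 in WT HDM, and 0 and 6 in KO-labelled HDM skin. The neutrophil chemokine gene Cxcl5 had 0 reads in both naive libraries and 917 and 914 in WT and KO-labelled HDM skin, close to each other. Defb3, a beta-defensin gene, had 928 reads in WT HDM and 138 in KO-labelled HDM, and the envelope genes Lce3a and Lce3b 1821 and 2003 against 425 and 265, with near-identical copies among them. Of the interleukin 20 family, Il19 had 206 reads in WT HDM and 390 in KO-labelled HDM, and Il24 25 and 141. Il31ra, the receptor gene of an itch cytokine, had 11 reads in WT HDM and 0 elsewhere. The type 2 cytokine genes Il4, Il5 and Il31 had 0 reads in every library, and Foxp3, a gene of regulatory T cells that lay above the filter, had 242, 197, 228 and 255 in WT naive, KO-labelled naive, WT HDM and KO-labelled HDM.

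Sex-linked transcripts divided naive from HDM libraries: beside Ddx3y, the Y-linked genes Uty, Eif2s3y and Kdm5d had 543, 219 and 36 reads in WT naive and 233, 454 and 16 in KO-labelled naive, against 1, 0 and 0 in WT HDM and 0 of each in KO-labelled HDM skin. Animals of different sex are a candidate explanation, and Xist and all of these Y-linked genes go in the direction it requires. To this, 4 X-linked genes that escape inactivation add little. Their median log2 difference with HDM was 0.64 in WT and 0.86 in KO-labelled skin, within the random lists (percentiles 92.6 and 92.8). In each genotype 1 of the 4 passed 2-fold, and Kdm6a stood at -0.49 in KO-labelled skin. That most of the HDM genes of the additive fit lie on X or Y is excluded, since 1.67% of them do, against 2.92% of measured genes. That share does not bear on effects of sex on other genes. Those are confounded with HDM throughout, since both naive libraries differ from both HDM libraries in these transcripts, and they stay open.

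Transcripts of other tissues also differed. Salivary gland tissue in the naive samples may account for Bpifa2 and its like: 12 of 17 other salivary genes, those with 10 or more reads in either library, were higher in WT naive than in WT HDM skin by a median of 1.90 (quartiles 0.57 and 6.90, 8 higher and 1 lower by 2-fold or more; Klk1 had 709 reads against 1), a value between the bounds set in advance, so this cannot be told apart from another source. For the missing cartilage transcripts and Krt2 of KO-labelled HDM skin, a sample of another body site without ear skin is a candidate explanation, as 7 of 17 trunk HOX genes, chosen by the same number of reads, were higher there than in WT HDM by a median of 2.27 (quartiles 1.33 and 3.40). It stays open, since the 2 above the expression filter, Hoxd8 and Hoxd9, stood at 0.85 and 0.48, and HOX genes of few reads also differed between libraries that kept cartilage transcripts: Hoxa5 was 5.61-fold and Hoxd9 3.70-fold higher with HDM in WT skin, and Hoxd9 5.43-fold and Hoxc6 at least 10.9-fold higher in KO-labelled than in WT naive skin. Loss of Egr1 alone is argued against by the cartilage median of -0.19 between the naive libraries (quartiles -0.82 and 0.27). Loss of Egr1 together with HDM stays open, because there is 1 such library. Another body site would also bear on the barrier, hair, sebaceous and matrix genes of that library, which was not tested. Cartilage markers were also lower in WT HDM than in WT naive skin (median -1.50), and a difference of body site between those libraries was not tested either.

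Genes at 0 reads in KO-labelled naive skin numbered 356 (3.41%) of 10443 genes with 50 reads or more in both WT libraries, and their share was 11.6% at 50 to 100 reads, 4.43% at 100 to 200, 0.644% at 200 to 500 and 0 of 2927 genes above. Lower depth is argued against, since the library held 104% of the median reads of the others. Silencing by loss of Egr1 in both treatments is argued against too, since 0.0479% of these genes (5) were at 0 in KO-labelled HDM skin. Silencing confined to naive skin stays open, because there is 1 such library. Fewer distinct RNA molecules in this library may be the source. Of 19 genes of ubiquitous complexes 0% were at 0 (upper bound 17.6%), against 10.1% of 2581 other genes of 50 to 200 reads. The 19 genes are too few to decide. This library also had 727 genes with 1 to 10 reads, against 1518 in WT naive, 2629 in WT HDM and 2181 in KO-labelled HDM. Had molecules been lost, counting intervals against this library would be too narrow. A filter in the authors' processing was not tested.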
